A study of Mus musculus with 27 samples.

How the data were processed

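RNA of 27 samples of primary microglia from newborn mice was measured by single-end sequencing with 75 bp reads. The labels describe 2 library protocols, TruSeq v2 on a HiSeq1500 and a SMART-Seq2 low-input protocol on a NextSeq500, without saying which library used which. Per the submitters' processing notes, CASAVA 1.8, kallisto and DESeq2 were used, with no role or order. The genome build and annotation release are not given in the sources used here. The authors deposited normalised counts, read here as a signal that is never negative: gene counts divided by a factor per library and gene. They are not whole numbers, and 34.0 to 60.9% of the low values per library were whole multiples of the smallest recurring step, within a tolerance of 0.01. Whole reads were therefore not recovered, so the tests on reads listed as alternatives were not run. The authors' batch-corrected table, on a log2 scale, served only as an alternative, and which batches it removed is not given.

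Groups were taken from the labels: genotype and stimulus, with replicates numbered in the order of the records where no label gave a number, so replicate numbers pair nothing. Library numbers in the titles form 2 series, 3012 to 3023 and 2048 to 2188, and unstimulated wild type is the one group with libraries in both. Genotype and series are otherwise the same split for stimulated cells. Values of 23995 genes were taken as log2(value + 1), and 14668 genes with a value of at least 10 in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with trend, two-sided, Benjamini-Hochberg). All 27 libraries entered 1 fit with group and number series, and a gene was called at an adjusted p under 0.05. Stimulus effects, their differences between genotypes, the unstimulated genotypes, pairs of stimuli in wild type and the number series were contrasts of that fit. Gene lists, 37 in all, covered functions, library quality and other cell types. They were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment within a comparison, separately for cell type lists and for the others. Camera calls printed without another p also passed with an estimated correlation. Lists of type I interferon genes and lymphocyte markers had fewer than 3 tested members and were not tested.

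The named genes follow a rule made before the data were examined, as were the tests, groups, lists and listed alternatives. It takes the 8 highest and 6 lowest log2 fold changes of each stimulus comparison, 8 and 8 of each difference between genotypes, and 4 and 4 of each stimulus pair. Each had to pass the threshold, reach a mean of at least 100 in the higher group and show no overlap between groups, and gene models without a symbol were left out. A panel of 14 genes and up to 4 examples per list were reported besides; other genes named as list examples, Gfap, Col1a1, Gm19220, Gm26822, Grip2 and the genes near Cnr2 were chosen after their values were seen. Positions are from GENCODE M21 on GRCm38, to which 23950 of 23995 gene identifiers matched. Members of multigene families (Gbp, Ifi, Slfn, H2, Serpina3, Ccl and Tgtp genes) share sequence, so reads may be split between them and their values are uncertain. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.

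Chi-square per degree of freedom, over genes with at least 20 approximate reads, ran from 4.10 to 75.7 over 27 replicate pairs. None were merged. The fit was tested on 13355 genes simulated with 1 dispersion (0.0154), 50 changed per size. Of genes changed 1.5, 2, 4 and 8-fold it recovered 30, 50, 50 and 50 for PolyI:C in wild type (15 wrongly called). The difference in PolyI:C response gave 5, 39, 50 and 50 (7 wrongly called). Uneven real spread may lower recovery. Quantile scaling moved the median log2 change of all genes by -0.11 (LPS in wild type), 0.14 (CpG in wild type), -0.12 (difference in CpG response), -0.28 (LPS against CpG) and -0.15 (PolyI:C against CpG), so list medians near 0 there are relative to these shifts. Alternatives varied the pseudocount, filter, scaling, series term, libraries in the fit, library weights, variance model, fold threshold and input table, and left out each library in turn.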

Results

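Microglia, the resident macrophages of the brain, were grown from newborn mice and their RNA was sequenced in 27 libraries. The cells were shaken off mixed glial cultures of cortex, and came from wild-type C57BL/6J mice or from CB2-/- mice, which were made to lack the cannabinoid receptor CB2 encoded by Cnr2. They were left unstimulated or treated for 16 h with LPS (100 ng/ml) plus interferon-γ (20 ng/ml), with PolyI:C, or with CpG (1 nmol/ml). LPS is a bacterial ligand of Toll-like receptor (TLR) 4, PolyI:C a double-stranded RNA analogue sensed by TLR3, and CpG an unmethylated DNA ligand of TLR9. The stated question is whether CB2 takes part in the activation of microglia through these receptors. There were 6 wild-type unstimulated libraries and 3 in each of the other 7 groups. Library numbers fall into 2 series: wild-type unstimulated replicates 1 to 3 and all stimulated wild-type libraries carry numbers 3012 to 3023, while all libraries labelled CB2-/- carry 2048 to 2059 and wild-type unstimulated replicates 4 to 6 carry 2186 to 2188. Wild-type responses were therefore measured against replicates 1 to 3, and the unstimulated genotypes were compared through replicates 4 to 6, so each of these comparisons stays within a number series as defined here. Whether libraries 2186 to 2188 were prepared together with 2048 to 2059 is not given in the labels, and neither is whether replicates came from separate animals or cultures, so p-values measure only the spread between these libraries. The summed normalised count per library ran from 6341300 to 14152000, about 2.50 to 36.7 M reads if the smallest recurring step in the values is taken as 1 read, and 13628 to 20643 of 23995 genes were above 0. Levels are given as normalised counts, mean ± SD over n = 3 libraries, and changes as log2 fold change ± SE on the log2(value + 1) scale, which understates the change of low genes.

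Cnr2, the gene targeted in the CB2-/- mice (chromosome 4, 135895394 to 135920207 in GRCm38, plus strand), was detected in every library labelled CB2-/-. Its normalised counts were 317, 411 and 454 in the unstimulated libraries labelled CB2-/-, 217, 229 and 234 with LPS and interferon-γ, 329, 412 and 368 with PolyI:C and 287, 301 and 319.5 with CpG. Wild-type unstimulated libraries held 178, 230.0 and 233 in replicates 1 to 3 and 172, 231 and 203 in replicates 4 to 6. All stimulated wild-type libraries were far lower, at 22, 18.3 and 20.7 with LPS and interferon-γ, 9.57, 7.32 and 16.2 with PolyI:C and 0, 2.78 and 16.1 with CpG. In wild-type cells Cnr2 fell with each stimulus (-3.32 ± 0.54, -4.22 ± 0.54 and -5.73 ± 0.54, the largest adjusted p being 2.16e-05, limma, BH). In the libraries labelled CB2-/- the changes were -0.78 ± 0.54, -0.08 ± 0.54 and -0.37 ± 0.54, with adjusted p of 0.355, 0.962 and 0.782 (limma, BH). The difference between the responses was 2.54 ± 0.77, 4.13 ± 0.77 and 5.36 ± 0.77 in the same order, with adjusted p of 0.0294, 2.46e-04 and 4.11e-05 (limma, BH). Without wild-type CpG replicate 1 or 3 the fall was -4.73 or -6.78 and the CpG difference 4.36 or 6.41, and the LPS difference missed the threshold without any 1 of 9 of the 12 compared libraries. Without stimulus the level in the libraries labelled CB2-/- lay above wild type by 0.95 ± 0.54, adjusted p = 0.296 (limma, BH), and in the authors' batch-corrected table by 0.94, which passed the threshold. A value per gene cannot show which part of Cnr2 was deleted, and it checks nothing where the counted transcript lies outside that part. The genotype therefore rests on the labels, as does every direction between genotypes given here.

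**Figure D1:**
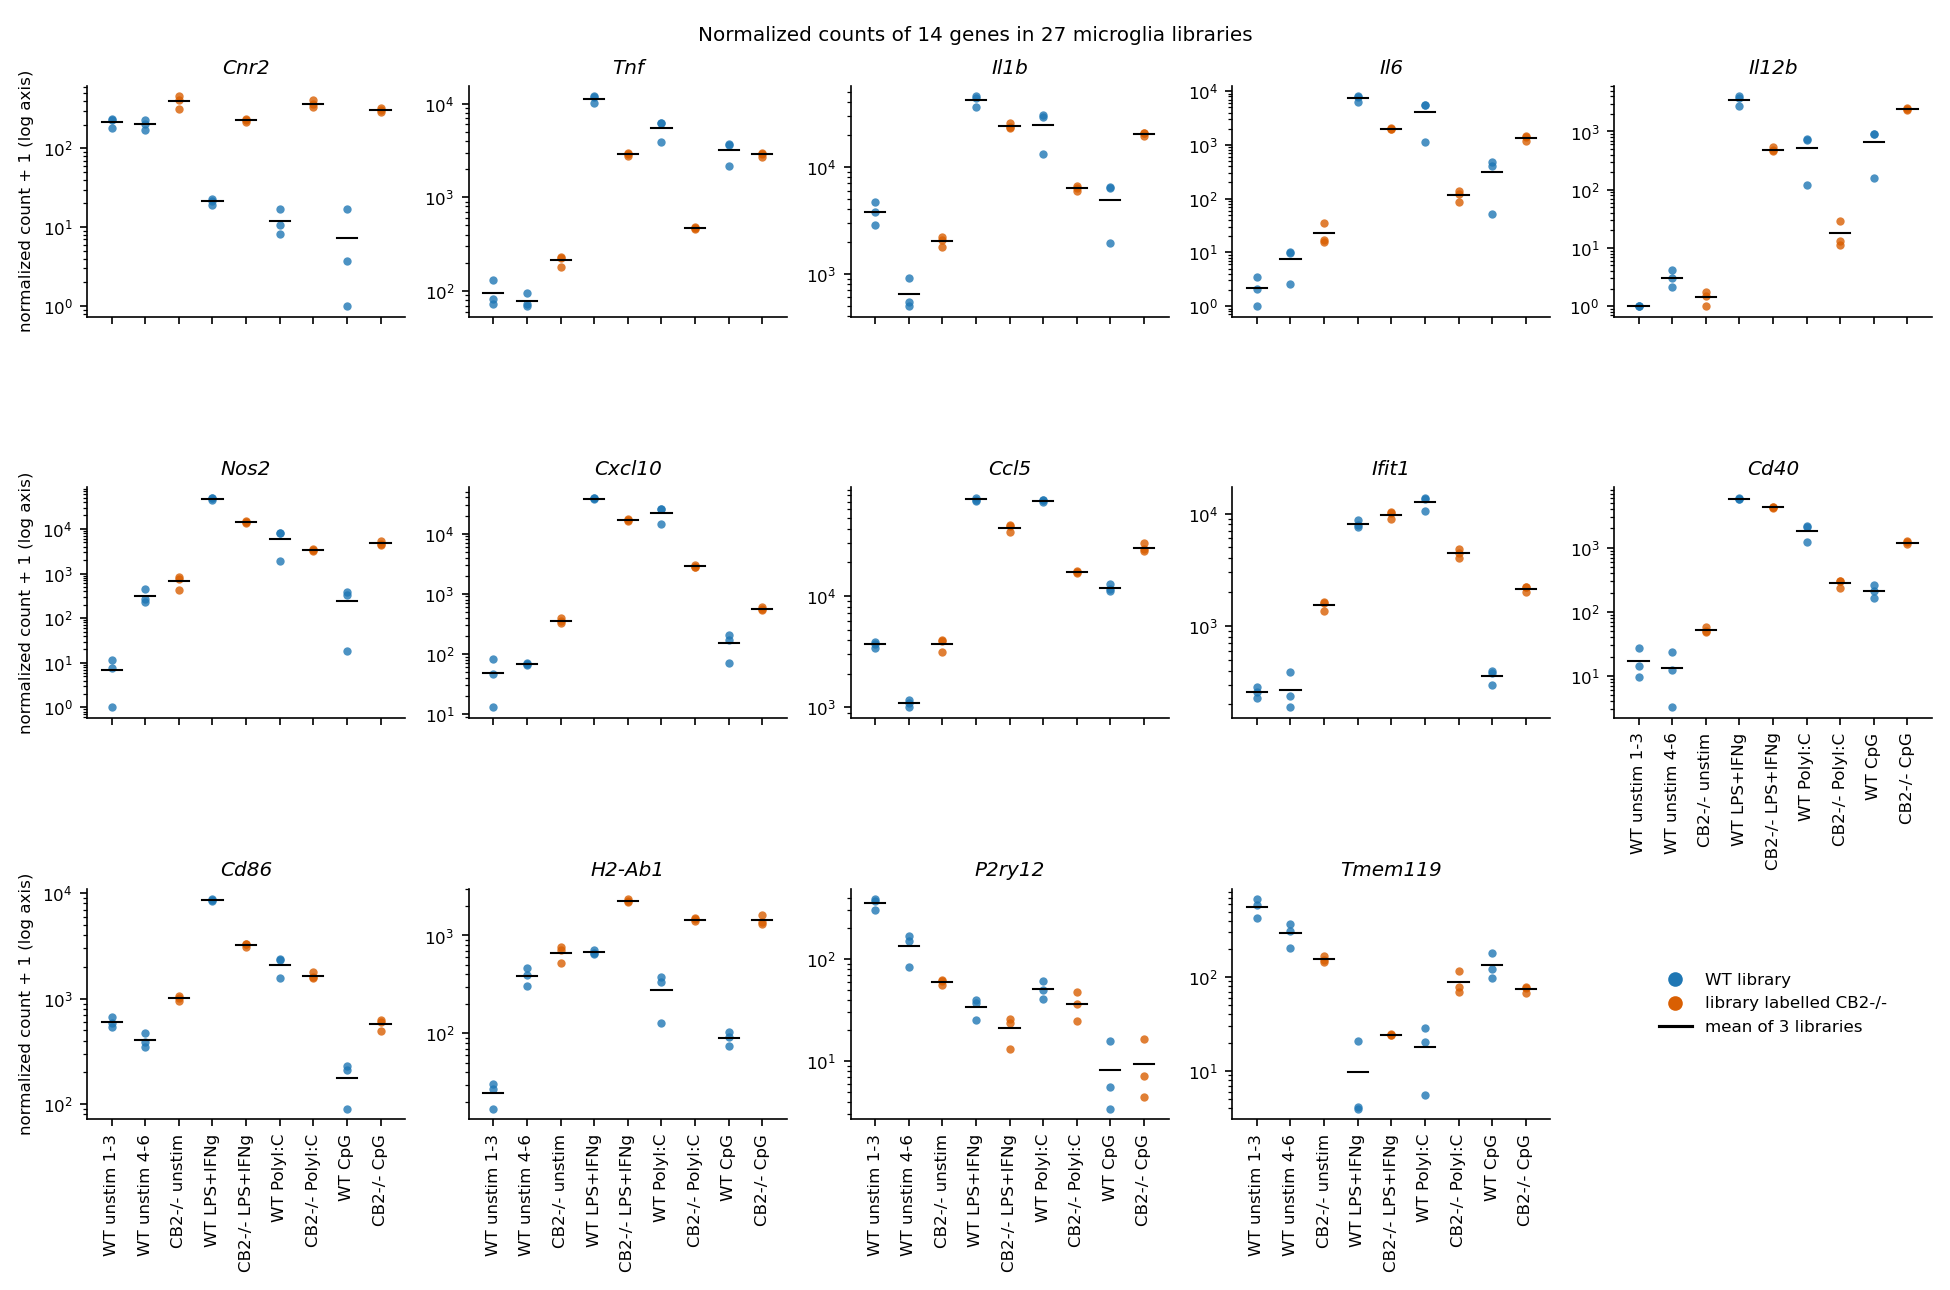
Normalised count plus 1 (log axis) of 14 genes fixed beforehand, in each of the 27 libraries by group, with dots for libraries (blue wild type, orange labelled CB2-/-) and bars for the mean of 3. Cnr2 lies between 217 and 454 in all libraries labelled CB2-/-, and at or below 22 in all stimulated wild-type libraries.

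Several measures that no comparison is about moved with the number series or with the genotype. Gm19220, Gm26822 and Grip2, which were singled out after their values were seen because they took very large shares of some libraries, together held at most 0.00453% of the summed values in the series 3012 to 3023. In the other series they held 0.0741 to 50.8%, with the highest share in the second PolyI:C library labelled CB2-/-. Mitochondrially encoded transcripts made up 1.50 to 3.20% in the first series and 0.242 to 1.42% in the other. Markers of astrocytes had a mean log2 level of 3.81 to 4.98 in the libraries labelled CB2-/- and 1.42 to 7.19 in wild type, and markers of fibroblasts and meninges 1.8 to 3.40 and 0.853 to 6.88. The lowest wild-type values of both marker sets were those of replicate 1 of the unstimulated, PolyI:C and CpG groups. Gfap, the astrocyte filament protein, stood at 1231 ± 339 in wild-type unstimulated replicates 4 to 6 and 71.1 ± 34.2 in the unstimulated libraries labelled CB2-/-, and Col1a1, a fibroblast collagen, at 525 ± 357 and 12 ± 3.49.

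**Figure D2:**
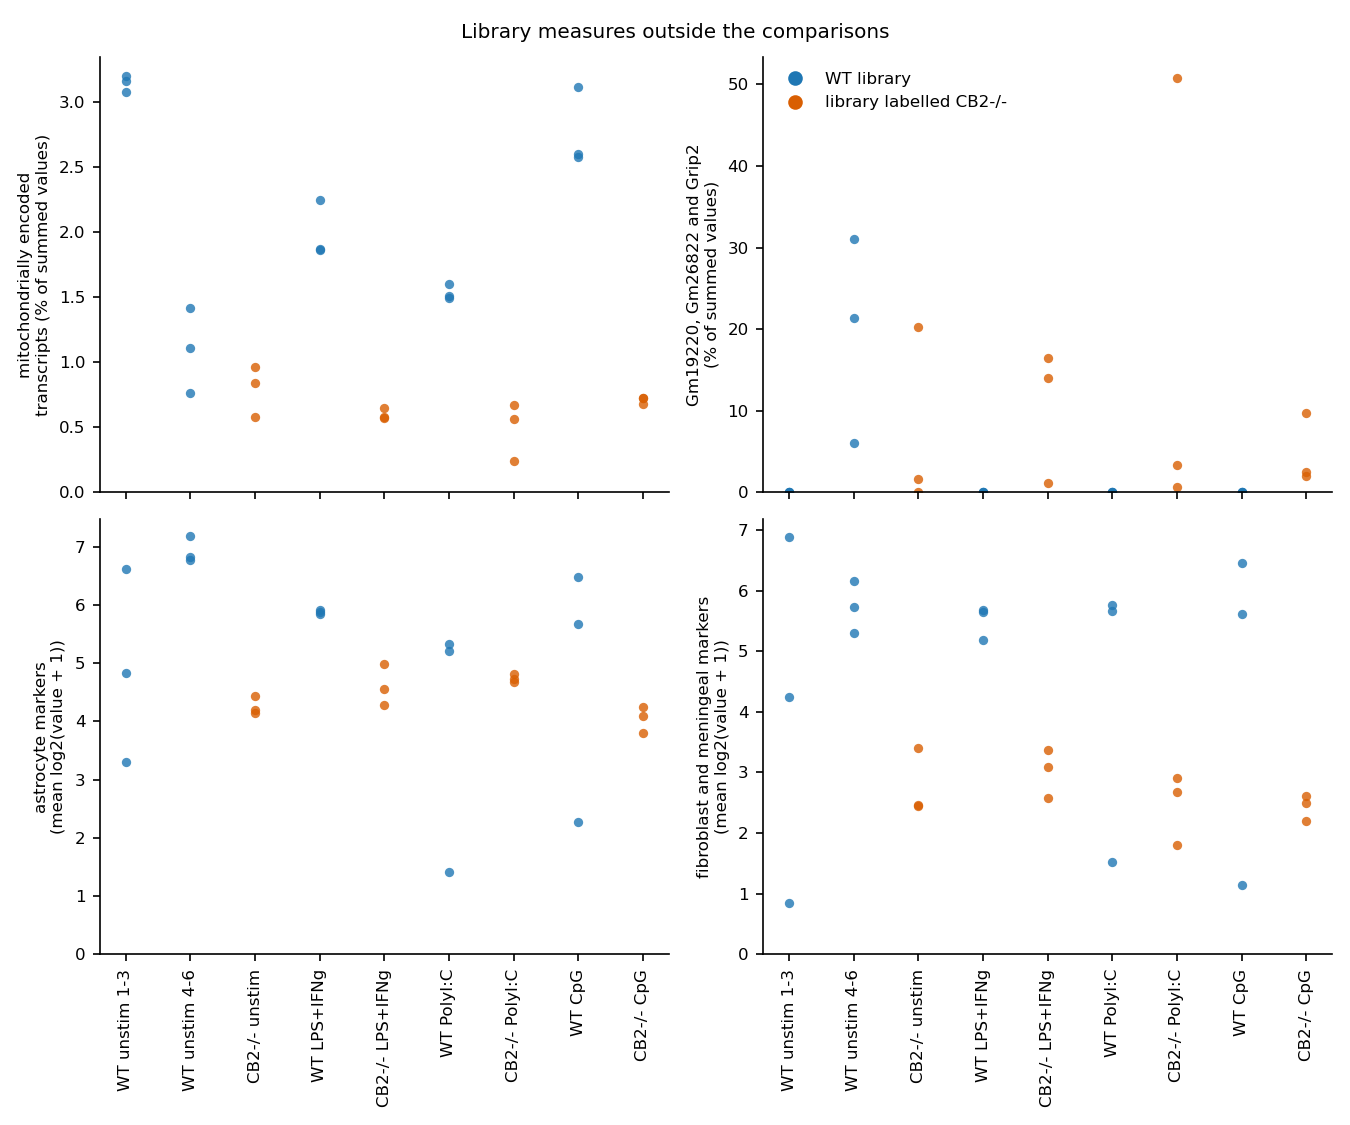
Share of the summed values (%) in mitochondrially encoded transcripts and in Gm19220, Gm26822 and Grip2, and mean log2(value + 1) of astrocyte and of fibroblast and meningeal markers, with 1 dot per library by group (blue wild type, orange labelled CB2-/-). Gm19220, Gm26822 and Grip2 together reach 50.8% in 1 library and stay near 0 in all 12 libraries of the series 3012 to 3023.

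The response of wild-type microglia to the TLR4 ligand with interferon-γ was led by Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), which rose from 5.75 ± 5.42 to 47885 ± 3036 normalised counts (13.39 ± 0.82). Cxcl9, a chemokine induced by interferon-γ, rose from 11.6 ± 17.7 to 27230.0 ± 435 (12.25 ± 0.93), and the cytokine Il6 from 1.17 ± 1.22 to 7364 ± 949.9 (11.90 ± 0.67). The collagenase Mmp13 reached 74444 ± 6292, and Mmp13, the uridine phosphorylase Upp1 and the protease inhibitor Serpina3f rose by 10.53 to 11.19 on the log2 scale. Il12b, the p40 subunit of interleukin-12, and Serpina3g were listed at 0 in wild-type unstimulated replicates 1 to 3 and reached 3511 ± 657 and 1406 ± 137. Among the genes that fell, the prostaglandin-degrading dehydrogenase Hpgd went from 3465 ± 487 to 12 ± 3.50 (-8.09 ± 0.36), and the organic anion transporter Slco2b1 went from 991 ± 179.6 to being listed at 0. The Ras exchange factor Rasgrp3, the oxysterol receptor Gpr183, Rtn4rl1 and the calpain Capn3 had log2 fold changes of -8.18 to -6.73. For these 14 genes the largest adjusted p was 1.83e-06 (limma, BH).

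Gene lists fixed before the data were examined are given by how many members passed the threshold, their median log2 fold change or difference and the camera test, and counts adjusted over the list alone were the same unless given. Inflammatory gene groups rose almost as a whole with LPS and interferon-γ in wild type. In the list of proinflammatory cytokines 15 of 16 rose and 0 fell, median log2 4.81, camera adjusted p = 1.35e-11, with Tnf (6.92) and Il1b (3.49) as examples. Chemokines behaved alike: 18 of 19 rose and 0 fell, median log2 4.96, camera adjusted p = 6.01e-12, including Cxcl10 (10.03) and Ccl5 (4.33). Among type I interferon response genes 31 of 31 rose and 0 fell, median log2 3.40, camera adjusted p = 2.38e-28, with Ifit1 (4.99) and Rsad2 (6.65) among them. The interferon-γ response GTPases, which act against intracellular pathogens, rose too: 16 of 16 rose and 0 fell, median log2 7.31, camera adjusted p = 1.03e-18. Of the MHC class I presentation genes 20 of 20 rose and 0 fell, median log2 2.74, camera adjusted p = 8.22e-22. Of costimulatory and checkpoint molecules 10 of 12 rose and 0 fell, median log2 4.50, camera adjusted p = 5.87e-08, with Cd40 (8.56) and Cd86 (3.86). In the NF-κB and feedback list 22 of 22 rose and 0 fell, median log2 2.60, camera adjusted p = 7.03e-19. In the list of nitric oxide, oxidant and itaconate enzymes 16 of 18 rose and 0 fell, median log2 3.39, camera adjusted p = 2.07e-12. Genes of glycolysis and glucose uptake showed 18 of 20 higher and 0 lower, median log2 1.99, camera adjusted p = 2.06e-10, adjusted p = 0.127 with an estimated correlation. The class II list was split: 6 of 11 rose and 3 fell, median log2 0.54, camera adjusted p = 0.130, median -0.08 with quantile scaling, with H2-Ab1 (4.81) among those that rose.

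Genes typical of resting microglia fell. For the homeostatic list 2 of 28 rose and 21 fell, median log2 -2.13, camera adjusted p = 1.27e-12, with Tmem119 (-6.29) and P2ry12 (-3.40) as examples, while Mertk (1.49) rose. Cholesterol biosynthesis and efflux genes gave 2 of 25 higher and 20 lower (2 and 21 adjusted over the list alone), median log2 -1.51, camera adjusted p = 1.28e-08. The list of unfolded protein and heat shock genes gave 18 of 19 higher and 0 lower, median log2 1.95, camera adjusted p = 4.60e-10. Markers of monocytes and neutrophils also moved, with 5 of 6 higher and 0 lower, median log2 3.03, camera adjusted p = 0.0339, adjusted p = 0.0717 with an estimated correlation. Ribosomal protein genes gave 0 of 32 higher and 20 lower, median log2 -0.45, camera adjusted p = 2.38e-05, adjusted p = 0.304 with an estimated correlation. Left out alone, wild-type unstimulated replicate 1 gave 12.32 for Nos2 and 9.27 for Cxcl10, replicate 2 gave 14.10 for Nos2, and wild-type LPS replicate 3 gave -7.08 for Tmem119. In all, 5830 genes passed the threshold, 3186 higher and 2644 lower, and with quantile scaling 2775 higher and 3254 lower (limma, BH).

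PolyI:C, the TLR3 ligand, raised cytokine and interferon-induced genes in wild-type microglia. Il6 (chromosome 5, 30013114 to 30019981) led, rising from 1.17 ± 1.22 to 4026 ± 2489 normalised counts (10.73 ± 0.67). Replicate 1, the library with the lowest astrocyte markers, held 1152, and the others 5421 and 5504; without it Il6 rose by 11.47. Mmp13 rose from 49.7 ± 9.07 to 81430.0 ± 31152 (10.58 ± 0.40), Slfn4, a Schlafen family member, from 8.23 ± 7.17 to 9233 ± 3636 and the siderophore-binding lipocalin Lcn2 from 18.1 ± 20.8 to 9440.1 ± 884. Nos2, the granulocyte colony-stimulating factor Csf3 and the anti-inflammatory cytokine Il10 rose by 9.40 to 10.11 on the log2 scale, and Il19, a cytokine of the interleukin-10 family, went from being listed at 0 to 1250.5 ± 751. Hpgd fell from 3465 ± 487 to 8.63 ± 2.54 (-8.51 ± 0.36), and Slco2b1, Capn3, Rasgrp3, the protease Htra3 and the hepatocyte growth factor gene Hgf had log2 fold changes of -8.50 to -6.55. Over these 14 genes the largest adjusted p was 9.03e-07 (limma, BH).

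All type I interferon response genes rose with PolyI:C in wild type: 31 of 31 rose and 0 fell, median log2 3.73, camera adjusted p = 6.83e-32, with Rsad2 (7.48), Ifit1 (5.62) and Oasl1 (5.87) as examples. Proinflammatory cytokines gave 13 of 16 higher and 0 lower (14 and 0 adjusted over the list alone), median log2 3.63, camera adjusted p = 2.10e-10, with Tnf (5.86), Il1b (2.62) and Il1a (8.09). In the chemokine list 15 of 19 rose and 1 fell, median log2 4.44, camera adjusted p = 4.99e-10, with Cxcl10 (9.18), Ccl5 (4.28) and Ccl4 (7.22). The GTPases of the interferon-γ response gave 14 of 16 higher and 0 lower, median log2 5.27, camera adjusted p = 1.13e-13. Costimulatory and checkpoint molecules gave 8 of 12 higher and 2 lower, median log2 2.84, camera adjusted p = 7.21e-05, adjusted p = 0.0954 with an estimated correlation, with Cd40 (6.85) and Cd86 (1.78). Homeostatic genes fell, with 0 of 28 higher and 24 lower (2 and 24 adjusted over the list alone), median log2 -2.24, camera adjusted p = 1.16e-14, with Gpr34 (-6.20), Tmem119 (-5.22) and P2ry12 (-2.82). So did cholesterol genes, with 2 of 25 higher and 21 lower, median log2 -1.93, camera adjusted p = 1.88e-09, with Sqle (-3.93) and Cyp51 (-3.25). The class II list moved both ways, with 2 of 11 higher and 5 lower, median log2 -0.17, camera adjusted p = 0.429, H2-Ab1 rising (3.40) and H2-DMa falling (-4.59). Markers of monocytes and neutrophils gave 5 of 6 higher and 0 lower, median log2 4.37, camera adjusted p = 0.00268. Mitochondrially encoded transcripts gave 0 of 13 higher and 10 lower (0 and 11 adjusted over the list alone), median log2 -1.26, camera adjusted p = 1.32e-05, adjusted p = 0.155 with an estimated correlation. Left out alone, wild-type unstimulated replicate 1 gave 9.03 for Nos2 and 8.43 for Cxcl10, replicate 2 gave 10.81 for Nos2, and wild-type PolyI:C replicate 1 gave 10.81 for Nos2 and -4.51 for Tmem119. Altogether 6032 genes passed the threshold, 3108 higher and 2924 lower, and with quantile scaling 2879 higher and 3073 lower (limma, BH).

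With the TLR9 ligand CpG, Il10 (chromosome 1, 131019845 to 131024974) led in wild-type microglia, rising from 0.246 ± 0.426 to 2176 ± 490.0 normalised counts (10.80 ± 0.77), and the dicarboxylate transporter Slc13a3 rose from 10.2 ± 1.50 to 13495 ± 8052 (10.10 ± 0.50). The myeloid receptor Cd300e, the gelatinase Mmp9 and Lcn2 rose by 7.98 to 9.61 on the log2 scale. Il12b, Draxin and Lad1 were listed at 0 in wild-type unstimulated replicates 1 to 3 and reached 658 ± 436, 541 ± 215 and 189 ± 48.2. Among the falls, the chemokine receptor Cxcr4 went from 1523 ± 122 to 7.27 ± 6.42 (-7.92 ± 0.41) and Entpd1, the ectonucleotidase CD39, from 1058 ± 99.1 to 8.12 ± 8.01. Slco2b1, Cytip, Hgf and Gpr34 had log2 fold changes of -7.95 to -7.74. The largest adjusted p over the 14 genes was 9.36e-09 (limma, BH).

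The interferon response did not rise as a group with CpG in wild type: of type I interferon response genes 3 of 31 rose and 15 fell (3 and 17 adjusted over the list alone), median log2 -0.64, camera adjusted p = 5.74e-04, adjusted p = 0.349 with an estimated correlation, with Ifit2 (-3.01) and Oas3 (-2.76) among those that fell and Ifit1 (0.48, a call lost without any 1 of 4 of the 6 compared libraries) among the few that rose. Cytokines and chemokines rose in part: for cytokines 8 of 16 rose and 2 fell (9 and 2 adjusted over the list alone), median log2 2.68, camera adjusted p = 5.05e-05, adjusted p = 0.177 with an estimated correlation, with Tnf (5.06) and Il6 (6.82) and with Il1b at 0.21 ± 0.34 (adjusted p = 0.676, limma, BH). Without replicate 1, which was low in astrocyte markers, Il1b rose by 0.79. For chemokines 12 of 19 rose and 2 fell, median log2 1.69, camera adjusted p = 5.05e-05, adjusted p = 0.244 with an estimated correlation, with Ccl4 (6.92), Cxcl10 (1.89) and Ccl5 (1.69). NF-κB and feedback regulators gave 19 of 22 higher and 2 lower, median log2 1.8, camera adjusted p = 5.71e-15, with Dusp2 (6.51) and Nfkbiz (4.52). In the nitric oxide, oxidant and itaconate list 14 of 18 rose and 3 fell, median log2 2.08, camera adjusted p = 3.10e-07, adjusted p = 0.131 with an estimated correlation, with Nos2 (4.89) and Ptges (7.43). Costimulatory and checkpoint molecules moved both ways, with 6 of 12 higher and 4 lower, median log2 1.04, camera adjusted p = 0.200, Cd40 (3.75) rising and Cd86 (-1.86) falling. The class II list gave 1 of 11 higher and 6 lower, median log2 -1.07, camera adjusted p = 0.0212, adjusted p = 0.308 with an estimated correlation, with H2-Ab1 (1.88, but -0.12 and not called without the series term) against the direction of the list. Homeostatic genes gave 1 of 28 higher and 23 lower (1 and 24 adjusted over the list alone), median log2 -1.76, camera adjusted p = 8.81e-15, with P2ry12 (-5.72), P2ry13 (-7.20) and Tmem119 (-2.09). Left out alone, wild-type unstimulated replicate 1 gave 3.81 for Nos2 and 1.14 for Cxcl10, replicate 2 gave 5.59 for Nos2, wild-type CpG replicate 1 gave 6.30 for Nos2, 7.85 for Il6 and -6.33 for P2ry12, replicate 2 gave 4.24 for Nos2 and 6.23 for Il6, and replicate 3 gave 4.12 for Nos2. By limma with BH, 5285 genes passed the threshold, 2415 higher and 2870 lower, and with quantile scaling 2564 higher and 2529 lower.

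**Figure D3:**
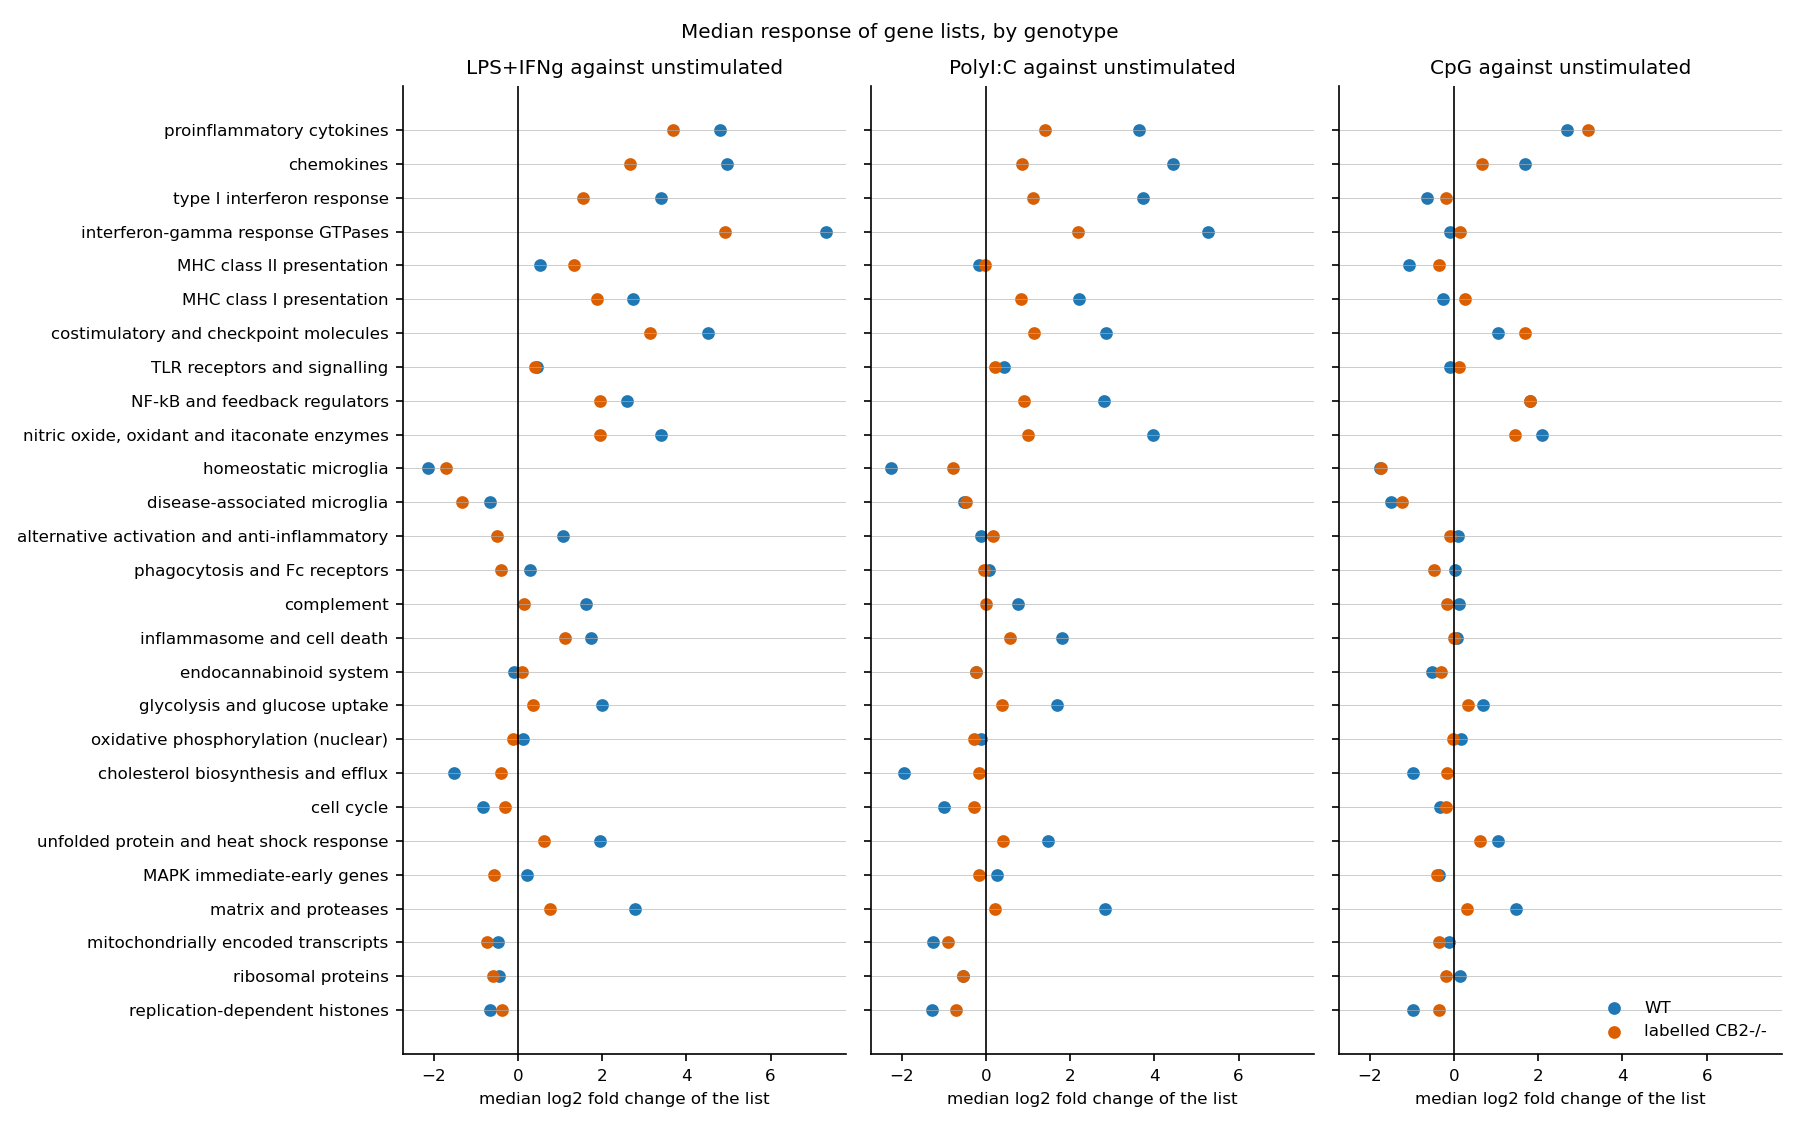
Median log2 fold change of each gene list of functions and library quality (horizontal axis) against unstimulated libraries for the 3 stimuli, with blue dots for wild type and orange dots for the libraries labelled CB2-/-. The type I interferon response lies at 3.40 and 1.55 for LPS with interferon-γ and at 3.73 and 1.11 for PolyI:C, and the sign changes with quantile or recomputed ratio scaling for MHC class II presentation, phagocytosis and Fc receptors and oxidative phosphorylation (nuclear) in wild type with LPS; phagocytosis and Fc receptors in wild type with PolyI:C; interferon-gamma response GTPases, phagocytosis and Fc receptors, cell cycle and ribosomal proteins in wild type with CpG; complement and endocannabinoid system in libraries labelled CB2-/- with LPS; complement in libraries labelled CB2-/- with PolyI:C.

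Set against each other, the stimuli separated in wild type. Compared with PolyI:C, LPS with interferon-γ gave higher Serpina3f (2612 ± 76.1 against 31.3 ± 28.4, 7.64 ± 0.99, chromosome 12, 104214544 to 104221129) and higher Serpina3g, the amino acid transporter Slc6a19 and the chloride channel family member Clic5 (5.94 to 7.26). It gave lower Il19 (36.0 ± 6.29 against 1250.5 ± 751), Ifitm7, Il10 and the haptoglobin gene Hp, with log2 differences of -4.81 to -3.74, the largest adjusted p of the 8 genes being 0.00146 (limma, BH). Interferon-γ GTPases were higher with LPS and interferon-γ, with 13 of 16 higher and 0 lower (14 and 0 adjusted over the list alone), median log2 1.84, camera adjusted p = 3.88e-15. So were class II genes, with 7 of 11 higher and 0 lower (8 and 0 adjusted over the list alone), median log2 1.42, camera adjusted p = 1.10e-07, with Ciita (5.37) and H2-Aa (5.31). Type I interferon response genes lay lower, with 0 of 31 higher and 11 lower (1 and 16 adjusted over the list alone), median log2 -0.48, camera adjusted p = 4.92e-09, adjusted p = 0.167 with an estimated correlation. Nos2, Il12b, Tnf and Cd86 were higher by 1.06 to 3.28, and the differences of Il6 (1.17 ± 0.67), Il1b (0.87 ± 0.34) and Ccl5 (0.05 ± 0.10) had adjusted p of 0.344, 0.120 and 0.864 (limma, BH). Without wild-type PolyI:C replicate 1, low in astrocyte markers, Nos2 missed the threshold at 2.58, Il12b differed by 2.25 and Il6 by 0.42. Mitochondrially encoded transcripts also differed, with 8 of 13 higher and 0 lower (10 and 0 adjusted over the list alone), median log2 0.82, camera adjusted p = 3.43e-07, adjusted p = 0.184 with an estimated correlation. Astrocyte markers gave 0 of 12 higher and 0 lower, median log2 1.85, camera adjusted p = 0.0241, adjusted p = 0.545 with an estimated correlation. Between these stimuli 1358 genes passed the threshold, 785 higher and 573 lower.

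LPS with interferon-γ was likewise set against CpG. Fam26f (3009 ± 183 against 1.05 ± 1.82, 10.87 ± 0.54, chromosome 10, 34126067 to 34127984), the guanylate-binding protein Gbp4, Serpina3f and Cxcl9 were higher with LPS and interferon-γ, by 10.57 to 10.87. Slc13a3, Raver2, the immune receptor Cd244 and Il10 were higher with CpG, with log2 differences of -6.79 to -5.22, the largest adjusted p of the 8 genes being 3.31e-05 (limma, BH). All type I interferon response genes were higher with LPS and interferon-γ, with 31 of 31 higher and 0 lower, median log2 3.98, camera adjusted p = 1.20e-39. So were MHC class I genes, with 20 of 20 higher and 0 lower, median log2 3.18, camera adjusted p = 4.10e-27. Tmem119 was lower (-4.20 ± 0.52) and P2ry12 higher (2.32 ± 0.49), so homeostatic genes went both ways, with 9 of 28 higher and 11 lower (9 and 13 adjusted over the list alone), median log2 -0.28, camera adjusted p = 0.293. Left out alone, wild-type LPS replicate 3 gave -4.99 for Tmem119, and wild-type CpG replicate 1 gave 2.94 for P2ry12. For this pair 4812 genes passed the threshold, 2887 higher and 1925 lower. With quantile scaling the split was 2122 higher and 2737 lower.

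PolyI:C gave higher interferon-induced genes than CpG, led by Slfn4 (9233 ± 3636 against 17.1 ± 24.9, 9.99 ± 0.86, chromosome 11, 83175186 to 83190216), Ifit1bl1, Ifit3b and Ifi208 (8.77 to 9.99). Slc13a3, Raver2, the sialyltransferase St6gal1 and Ppic were higher with CpG, with log2 differences of -5.02 to -3.55, and the largest adjusted p of the 8 genes was 0.0228 (limma, BH). Genes of the type I interferon response gave 31 of 31 higher and 0 lower, median log2 4.22, camera adjusted p = 1.68e-49. Il12b differed by -0.34 ± 0.59, with adjusted p = 0.723 (limma, BH), while Nos2, Il6 and Il1b were higher with PolyI:C by 2.41 to 5.22. When omitted singly, wild-type CpG replicate 1 gave -1.19 for Il12b, 3.81 for Nos2 and 2.87 for Il6, replicate 2 gave 5.87 for Nos2 and 4.49 for Il6, replicate 3 gave 5.99 for Nos2, and wild-type PolyI:C replicate 1 gave 0.52 for Il12b, 5.92 for Nos2 and 4.66 for Il6. Mitochondrially encoded transcripts gave 0 of 13 higher and 9 lower, median log2 -1.15, camera adjusted p = 1.76e-06, adjusted p = 0.103 with an estimated correlation. In this comparison 4412 genes passed the threshold, 2578 higher and 1834 lower, and with quantile scaling 1985 higher and 2268 lower.

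Before any stimulus, interferon-induced genes stood higher in the libraries labelled CB2-/- than in wild-type replicates 4 to 6. Ifit1bl1 (chromosome 19, 34592891 to 34601956) was at 325 ± 43.5 against 12.6 ± 11.4 normalised counts (5.47 ± 0.78), Ms4a4c at 417 ± 31.4 against 15.3 ± 6.25 (4.76 ± 0.33), and the monocyte chemoattractants Ccl2 and Ccl7, with Slfn1, Pira2, Ifi208 and Ifi205, were higher by 3.75 to 4.79. Lower were C77080 (7.41 ± 9.72 against 263 ± 54.5, -5.62 ± 0.70), a gene on chromosome 4 as Cnr2 is, the imprinted RNA H19, the collagen Col6a1, A2m, Atp1b2, Ntrk2, the astrocytic glutamate transporter Slc1a3 and Mir6236, with log2 differences of -5.62 to -2.38. Over the 16 genes the largest adjusted p was 0.0358 (limma, BH).

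The type I interferon response list was higher as a whole without stimulus: 31 of 31 were higher and 0 lower, median log2 1.75, camera adjusted p = 1.33e-56, with Ifit3 (2.93), Isg15 (2.87) and Ifit1 (2.57). MHC class I genes gave 18 of 20 higher and 0 lower, median log2 1.19, camera adjusted p = 8.14e-35, with H2-Q6 (2.65) and H2-T22 (2.28). Interferon-γ GTPases gave 12 of 16 higher and 0 lower (13 and 0 adjusted over the list alone), median log2 2.15, camera adjusted p = 6.58e-18. Chemokines gave 9 of 19 higher and 0 lower (13 and 0 adjusted over the list alone), median log2 1.56, camera adjusted p = 6.45e-10, with Cxcl10 (2.38) and Ccl5 (1.75). Of the cytokines 4 of 16 were higher and 1 lower (7 and 1 adjusted over the list alone), median log2 0.59, camera adjusted p = 0.00253, adjusted p = 0.242 with an estimated correlation, with Tnf (1.43) and Il1b (1.68) higher. Of the costimulatory molecules 6 of 12 were higher and 0 lower, median log2 1.20, camera adjusted p = 3.94e-06, adjusted p = 0.0543 with an estimated correlation, with Cd40 (2.39) and Cd86 (1.32). Homeostatic genes gave 0 of 28 higher and 7 lower (1 and 11 adjusted over the list alone), median log2 -0.44, camera adjusted p = 5.43e-04, adjusted p = 0.184 with an estimated correlation, with Cx3cr1 (-1.43) and Gas6 (-1.41), and P2ry12 at -1.11 ± 0.49 (adjusted p = 0.168) and Tmem119 at -0.88 ± 0.52 (adjusted p = 0.311, limma, BH). Other measures differed between the same libraries: astrocyte markers gave 0 of 12 higher and 1 lower (0 and 8 adjusted over the list alone), median log2 -2.62, camera adjusted p = 1.88e-04, adjusted p = 0.576 with an estimated correlation. Fibroblast and meningeal markers gave 0 of 13 higher and 1 lower (0 and 6 adjusted over the list alone), median log2 -3.11, camera adjusted p = 0.00153, adjusted p = 0.577 with an estimated correlation. Mitochondrially encoded transcripts gave 0 of 13 higher and 9 lower (0 and 10 adjusted over the list alone), median log2 -1.0, camera adjusted p = 2.56e-13. By limma with BH, 1452 genes passed the threshold, 917 higher and 535 lower. With only the compared libraries fitted the split was 457 higher and 454 lower, and without the series term 1210 and 999. The count was 902 without unstimulated replicate 2 labelled CB2-/-, 819 without wild-type unstimulated replicate 5 and 859 without replicate 6. Cd40 differed by 3.03 without wild-type replicate 5 and by 1.59 without replicate 6. Leaving out the 4 libraries with over 20% in Gm19220, Gm26822 and Grip2 was chosen after seeing the data. It reduced wild type to replicate 4 and the libraries labelled CB2-/- to replicates 1 and 2, so no count is given. The median log2 of the type I interferon response list was then 1.64.

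The libraries labelled CB2-/- responded to LPS with interferon-γ as well. Tgtp1, an interferon-γ-induced GTPase (chromosome 11, 48985327 to 48994172), rose from 2.02 ± 2.33 to 2006 ± 204 normalised counts (9.70 ± 0.83), Cxcl9 from 10.6 ± 8.05 to 7959 ± 222 (9.64 ± 0.93) and Il6 from 21.6 ± 11 to 1994 ± 32.1 (6.57 ± 0.67). Il12b, Serpina3f, Clic5 and the hyaluronan synthase Has1 rose by 6.37 to 8.96, and Serpina3g went from being listed at 0 to 248 ± 13.6. Slco2b1 fell from 1296 ± 102 to 11.3 ± 11 (-7.09 ± 0.76), and Hpgd, Rasgrp3, the cyclooxygenase-1 gene Ptgs1, Gpr183 and Tpbgl had log2 fold changes of -6.72 to -4.90, the largest adjusted p of the 14 genes being 5.53e-06 (limma, BH). Interferon-γ GTPases gave 16 of 16 higher and 0 lower, median log2 4.91, camera adjusted p = 2.00e-23. Type I interferon response genes gave 29 of 31 higher and 0 lower, median log2 1.55, camera adjusted p = 7.11e-23, with Ifit1 (2.67) and Rsad2 (2.93). Cytokines gave 14 of 16 higher and 1 lower, median log2 3.68, camera adjusted p = 7.97e-12, with Tnf (3.77) and Il1b (3.59). Chemokines gave 13 of 19 higher and 0 lower (13 and 1 adjusted over the list alone), median log2 2.65, camera adjusted p = 1.97e-09, with Cxcl10 (5.57) and Ccl5 (3.49). Nos2, Cd40, Cd86 and H2-Ab1 rose by 1.68 to 6.37. Homeostatic genes gave 1 of 28 higher and 23 lower, median log2 -1.70, camera adjusted p = 3.59e-15, with Cx3cr1 (-3.40), Tmem119 (-2.66) and P2ry12 (-1.57). Disease-associated microglia genes gave 4 of 25 higher and 18 lower, median log2 -1.33, camera adjusted p = 1.97e-09, with Spp1 (-3.75) and Ank (-3.78). P2ry12 missed the threshold without any 1 of 3 of the 6 compared libraries. Mitochondrially encoded transcripts gave 0 of 13 higher and 9 lower (0 and 11 adjusted over the list alone), median log2 -0.73, camera adjusted p = 2.47e-05, adjusted p = 0.147 with an estimated correlation. By limma with BH, 3471 genes passed the threshold, 1879 higher and 1592 lower, and with quantile scaling 1647 higher and 1994 lower.

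PolyI:C raised interferon-induced genes in the libraries labelled CB2-/- too. The guanylate-binding protein Gbp5 (chromosome 3, 142493978 to 142522344) rose from 163 ± 16.1 to 1361 ± 91.7 normalised counts (3.06 ± 0.53), Cxcl10 from 354 ± 35.3 to 2851 ± 149 (3.01 ± 0.41) and AW112010 from 282 ± 30.5 to 1908 ± 185. Slfn4, Slco3a1, Celsr3, H2-M2 and Olfr56 rose by 2.72 to 2.94. Hpgd fell from 419 ± 77.2 to 50.8 ± 14.5 (-3.04 ± 0.36), and Ptgs1, Rasgrp3, the osteopontin gene Spp1, the transporter Abca9 and Rnase4 had log2 fold changes of -2.59 to -1.95, with a largest adjusted p of 0.0411 over the 14 genes (limma, BH). The type I interferon response list gave 24 of 31 higher and 0 lower (27 and 0 adjusted over the list alone), median log2 1.11, camera adjusted p = 1.08e-27, with Rsad2 (2.07), Mx1 (2.01) and Ifit1 (1.53). MHC class I genes gave 17 of 20 higher and 0 lower (19 and 0 adjusted over the list alone), median log2 0.83, camera adjusted p = 2.38e-21. Interferon-γ GTPases gave 14 of 16 higher and 0 lower, median log2 2.20, camera adjusted p = 1.08e-17. Of the cytokines 8 of 16 rose and 0 fell (10 and 0 adjusted over the list alone), median log2 1.40, camera adjusted p = 6.98e-08, with Tnf (1.15), Il1b (1.65), Il6 (2.44) and Il12b (3.57). Of the chemokines 7 of 19 rose and 0 fell (9 and 0 adjusted over the list alone), median log2 0.85, camera adjusted p = 5.52e-06, adjusted p = 0.0995 with an estimated correlation, with Ccl5 (2.16). Homeostatic genes gave 0 of 28 higher and 11 lower (0 and 15 adjusted over the list alone), median log2 -0.79, camera adjusted p = 5.79e-10, with Pros1 (-1.50) and Trem2 (-1.18), and P2ry12 at -0.77 ± 0.49 (adjusted p = 0.421), Tmem119 at -0.85 ± 0.52 (adjusted p = 0.384) and Nos2 at 2.40 ± 0.82 (adjusted p = 0.0740, limma, BH). Il6 missed the threshold without any 1 of 4 of the 6 compared libraries. Mitochondrially encoded transcripts gave 0 of 13 higher and 9 lower (0 and 12 adjusted over the list alone), median log2 -0.90, camera adjusted p = 7.80e-11. In total 1254 genes passed the threshold, 750 higher and 504 lower, and with quantile scaling 678 higher and 787 lower. The count was 805 without unstimulated replicate 1 labelled CB2-/- and 829 without replicate 2, and 773 without the 4 libraries holding over 20% in Gm19220, Gm26822 and Grip2, which were chosen after seeing the data.

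CpG raised Il12b (chromosome 11, 44400063 to 44414033) from 0.409 ± 0.378 to 2445 ± 61.0 normalised counts in the libraries labelled CB2-/- (10.80 ± 0.59), Il10 from 3.17 ± 3.38 to 611 ± 19.2 (7.63 ± 0.77) and Slc13a3 from 18.3 ± 7.34 to 1870.0 ± 154 (6.68 ± 0.50). Csf3, Zfp811, Cd300e, Shisa3 and the MAP kinase phosphatase Dusp2 rose by 6.21 to 7.17. Slco2b1 fell from 1296 ± 102 to 14.9 ± 15 (-6.76 ± 0.76), and Ptgs1, Hpgd, the G-protein regulator Rgs2, Rnase4 and the growth factor Fgf2 had log2 fold changes of -5.96 to -4.63, with a largest adjusted p of 0.00140 over the 14 genes (limma, BH). NF-κB and feedback regulators gave 20 of 22 higher and 0 lower (22 and 0 adjusted over the list alone), median log2 1.8, camera adjusted p = 1.76e-34. Cytokines gave 11 of 16 higher and 1 lower (11 and 2 adjusted over the list alone), median log2 3.19, camera adjusted p = 9.52e-12, with Tnf (3.77), Il1b (3.33) and Il6 (5.98). Chemokines gave 7 of 19 higher and 0 lower (8 and 1 adjusted over the list alone), median log2 0.67, camera adjusted p = 4.72e-06, adjusted p = 0.148 with an estimated correlation, with Ccl3 (4.11), Ccl4 (3.78) and Ccl5 (2.89). The type I interferon response list did not rise, with 1 of 31 higher and 7 lower (4 and 7 adjusted over the list alone), median log2 -0.18, camera adjusted p = 0.112, with Ifit2 (-1.32) and Ifit3 (-0.92) among those that fell. Homeostatic genes gave 1 of 28 higher and 20 lower (1 and 22 adjusted over the list alone), median log2 -1.72, camera adjusted p = 5.13e-20, with P2ry12 (-2.88), P2ry13 (-2.97) and Gpr34 (-3.92). Nos2 and Cd40 rose by 2.87 to 4.54 and Cd86 fell (-0.81 ± 0.22), with Cxcl10 at 0.67 ± 0.41 (adjusted p = 0.366), Ifit1 at 0.48 ± 0.17 (adjusted p = 0.0690) and Tmem119 at -1.07 ± 0.52 (adjusted p = 0.211, limma, BH). Both Nos2 and Cd86 missed the threshold without unstimulated replicate 1 or without CpG replicate 3 labelled CB2-/-. Border-associated macrophage markers gave 0 of 9 higher and 5 lower, median log2 -1.03, camera adjusted p = 0.0139, adjusted p = 0.149 with an estimated correlation. In these libraries 2092 genes passed the threshold, 1000 higher and 1092 lower.

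Whether the responses differed between genotypes was tested as the difference of log2 fold changes, libraries labelled CB2-/- minus wild type, each against unstimulated libraries of its own number series, and higher and lower refer to that difference. Genotype and number series coincide for stimulated cells, so a stimulus effect that differs between series cannot be separated from one that differs between genotypes. With LPS and interferon-γ a lower response was led by Nos2 (-8.93 ± 1.16), which reached 14211 ± 807 from 669.9 ± 215 in the libraries labelled CB2-/- and 47885 ± 3036 from 5.75 ± 5.42 in wild type, whose unstimulated replicates 4 to 6 held 313 ± 114. Ccl7 (-7.62 ± 1.26), Ccl2, Mmp13, Upp1, AA467197 and Pdpn, the membrane glycoprotein podoplanin, responded less in the libraries labelled CB2-/-, by -8.93 to -5.92 over these 7 genes. Il12rb1 was listed at 0 in wild-type unstimulated replicates 1 to 3 and reached 124 ± 24.7, against 7.78 ± 6.18 and 9.62 ± 3.36 in the libraries labelled CB2-/-. In the other direction, Pxdc1, Tmem176b, the taurine synthesis gene Csad, Col27a1, Capn3, Abhd15, Tmem119 and the amino acid oxidase Il4i1 differed by 3.53 to 4.24. Tmem119 went from 154 ± 11.5 to 23.4 ± 0.241 in the libraries labelled CB2-/- and from 559 ± 129 to 8.64 ± 9.65 in wild type. For these 16 genes the largest adjusted p was 0.0326 (limma, BH).

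Type I interferon response genes rose less with LPS and interferon-γ in the libraries labelled CB2-/-: 0 of 31 responded more and 28 less (0 and 30 adjusted over the list alone), median log2 -1.81, camera adjusted p = 1.16e-29, with Rsad2 (-3.72), Ifit1 (-2.31) and Oasl1 (-3.31). Chemokines gave 0 of 19 higher and 10 lower (0 and 11 adjusted over the list alone), median log2 -2.33, camera adjusted p = 7.53e-09, with Cxcl10 (-4.46), Ccl12 (-4.88) and Ccl5 (-0.84). Cytokines gave 1 of 16 higher and 7 lower (1 and 11 adjusted over the list alone), median log2 -2.24, camera adjusted p = 9.40e-05, adjusted p = 0.128 with an estimated correlation, with Il6 (-5.33), Tnf (-3.16) and Il1a (-4.46) but with Il1b at 0.09 ± 0.48 (adjusted p = 0.939, limma, BH). Interferon-γ GTPases gave 0 of 16 higher and 10 lower (0 and 11 adjusted over the list alone), median log2 -2.14, camera adjusted p = 1.73e-10. Glycolysis and glucose uptake genes gave 0 of 20 higher and 15 lower (0 and 16 adjusted over the list alone), median log2 -1.39, camera adjusted p = 1.09e-12, adjusted p = 0.0959 with an estimated correlation, with Hk3 (-2.65) and Pgk1 (-2.73). H2-Ab1, Cd40 and Cd86 responded less by -3.03 to -2.17, although H2-Ab1 reached 2258 ± 76.4 there and 676 ± 29.4 in wild type. Unstimulated wild-type replicates 4 to 6 themselves lay above replicates 1 to 3 by 6.08 for Nos2, 3.99 for H2-Ab1 and a median of 1.73 for glycolysis genes, while cholesterol genes lay lower there (median -0.98). Cholesterol genes, which fell in wild type, gave 15 of 25 higher and 1 lower (18 and 2 adjusted over the list alone), median log2 1.52, camera adjusted p = 1.04e-11, with Insig1 (2.32) and Cyp51 (2.20). Homeostatic genes gave 8 of 28 higher and 2 lower (11 and 2 adjusted over the list alone), median log2 0.69, camera adjusted p = 1.46e-04, adjusted p = 0.130 with an estimated correlation. When omitted singly, wild-type unstimulated replicate 1 gave -7.85 for Nos2 and -3.70 for Cxcl10, replicate 2 gave -9.63 for Nos2, and wild-type LPS replicate 3 gave 4.42 for Tmem119. Cd40 missed the threshold at -1.85 without wild-type unstimulated replicate 2. Between the genotypes 1810 genes passed the threshold, 584 higher and 1226 lower (limma, BH), and with quantile scaling 813 higher and 1002 lower.

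Of the 3 stimuli, PolyI:C gave the most genes whose response differed between the genotypes. Mmp13 reached 3247 ± 97.3 from 1012 ± 155 in the libraries labelled CB2-/- and 81430.0 ± 31152 from 49.7 ± 9.07 in wild type (-8.88 ± 0.56, chromosome 9, 7272514 to 7283331), and Il6 115 ± 25.7 from 21.6 ± 11 against 4026 ± 2489 from 1.17 ± 1.22 (-8.29 ± 0.94). Over Mmp13, Il6, Il10, Pdpn, Ccl7 and Nos2 the differences were -8.88 to -7.71. Il19 was listed at 0 without stimulus in both genotypes and reached 1250.5 ± 751 in wild type and 0.401 ± 0.694 in the libraries labelled CB2-/-. Draxin was listed at 0 in wild-type unstimulated replicates 1 to 3 and in the PolyI:C libraries labelled CB2-/-, and stood at 196 ± 67.7 in wild type with PolyI:C. Genes that fell in wild type had higher values in the libraries labelled CB2-/-: Slco2b1 was at 320.1 ± 85.9 there and at 3.16 ± 4.50 in wild type with PolyI:C (6.45 ± 1.07), and Cxcr4 at 891 ± 52.2 and 23.9 ± 6.94 (5.36 ± 0.57). With Htra3, Capn3, the transcription factor Mlxipl, Tmem37, Hpgd and AF529169, the differences of these 8 genes were 5.32 to 6.45. The largest adjusted p of the 16 genes was 0.00135 (limma, BH).

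Every type I interferon response gene rose less with PolyI:C in the libraries labelled CB2-/-: 0 of 31 responded more and 31 less, median log2 -2.82, camera adjusted p = 1.43e-32, with Rsad2 (-5.41), Ifit1 (-4.10) and Usp18 (-4.26). Chemokines gave 1 of 19 higher and 11 lower, median log2 -2.90, camera adjusted p = 1.16e-08, with Cxcl10 (-6.18), Ccl4 (-6.34) and Ccl5 (-2.12). Cytokines gave 0 of 16 higher and 10 lower (0 and 11 adjusted over the list alone), median log2 -2.99, camera adjusted p = 3.75e-09, with Tnf (-4.72), Csf3 (-6.57) and Il1a (-6.08) but with Il1b at -0.97 ± 0.48 (adjusted p = 0.148, limma, BH). Without wild-type PolyI:C replicate 1 Il1b passed the threshold at -1.37, and P2ry12 missed it without this or any 1 of 8 further libraries of the 12 compared (1.83 to 2.08). Cd40, Cd86 and H2-Ab1 responded less by -4.44 to -1.07. Homeostatic genes gave 20 of 28 higher and 2 lower (22 and 2 adjusted over the list alone), median log2 1.62, camera adjusted p = 1.74e-12, with Tmem119 (4.37), Cx3cr1 (3.52) and P2ry12 (2.05). Cholesterol genes too gave 20 of 25 higher and 1 lower (22 and 2 adjusted over the list alone), median log2 2.03, camera adjusted p = 1.24e-09, with Sqle (3.65). Markers of monocytes and neutrophils gave 0 of 6 higher and 5 lower, median log2 -3.44, camera adjusted p = 0.00612. When omitted singly, wild-type unstimulated replicate 1 gave -6.64 for Nos2 and -5.42 for Cxcl10, replicate 2 gave -8.41 for Nos2, and wild-type PolyI:C replicate 1 gave -9.04 for Il6, -8.41 for Nos2 and 3.66 for Tmem119. By limma with BH, 3636 genes passed the threshold, 1591 higher and 2045 lower.

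For CpG the differences went both ways. Slc40a1, the iron exporter ferroportin (chromosome 1, 45908068 to 45926523), went from 289 ± 57.3 to 226 ± 30.9 in the libraries labelled CB2-/- and from 269 ± 89.0 to 4.20 ± 5.33 in wild type (5.94 ± 0.83), and Entpd1 from 759.7 ± 54.8 to 163 ± 19.7 and from 1058 ± 99.1 to 8.12 ± 8.01 in the same order (5.38 ± 0.82). Cytip, Cdk5r1, the arginase Arg2, Cnr2, Amz1 and the clone-named model CT009754.3 were also higher in the libraries labelled CB2-/-, the 8 genes spanning 4.78 to 6.39. Mmp9 (-5.41 ± 0.95), Prss46, Ndrg1, Ifitm7, Raver2, Mmp13 and Ccl7 responded less, by -6.12 to -4.57, and Draxin, listed at 0 in wild-type unstimulated replicates 1 to 3, reached 541 ± 215 in wild type and 8.39 ± 3.33 in the libraries labelled CB2-/-. The largest adjusted p of the 16 genes was 0.0393 (limma, BH). Il1b (3.12) and Ccl5 (1.20) responded more and Tnf (-1.29) less, with Il6 at -0.84 ± 0.94 (adjusted p = 0.643), Nos2 at -2.02 ± 1.16 (adjusted p = 0.295) and Cd40 at 0.79 ± 0.61 (adjusted p = 0.466, limma, BH). Nos2 itself reached 4718 ± 484 in the libraries labelled CB2-/- and 240 ± 195 in wild type. Its series difference given for LPS applies here. Without wild-type CpG replicate 1, low in astrocyte markers, Nos2 passed the threshold at -3.43, Il6 stood at -1.87 and P2ry12 at 3.46. In the authors' batch-corrected table Il6 turned to 0.92 and passed it. Il12b, listed at 0 in wild-type unstimulated replicates 1 to 3, reached 658 ± 436 in wild type and 2445 ± 61.0 in the libraries labelled CB2-/-, but its difference in response missed the threshold (adjusted p = 0.171, limma, BH). Type I interferon response genes gave 8 of 31 higher and 2 lower (12 and 2 adjusted over the list alone), median log2 0.50, camera adjusted p = 0.00253, adjusted p = 0.564 with an estimated correlation. Homeostatic genes gave 10 of 28 higher and 1 lower (11 and 1 adjusted over the list alone), median log2 0.70, camera adjusted p = 0.00224, adjusted p = 0.438 with an estimated correlation, with P2ry13 (4.23), P2ry12 (2.84) and Csf1r (1.96). For CpG 1726 genes passed the threshold, 896 higher and 830 lower, or 880 and 911 with quantile scaling (limma, BH).

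**Figure D4:**
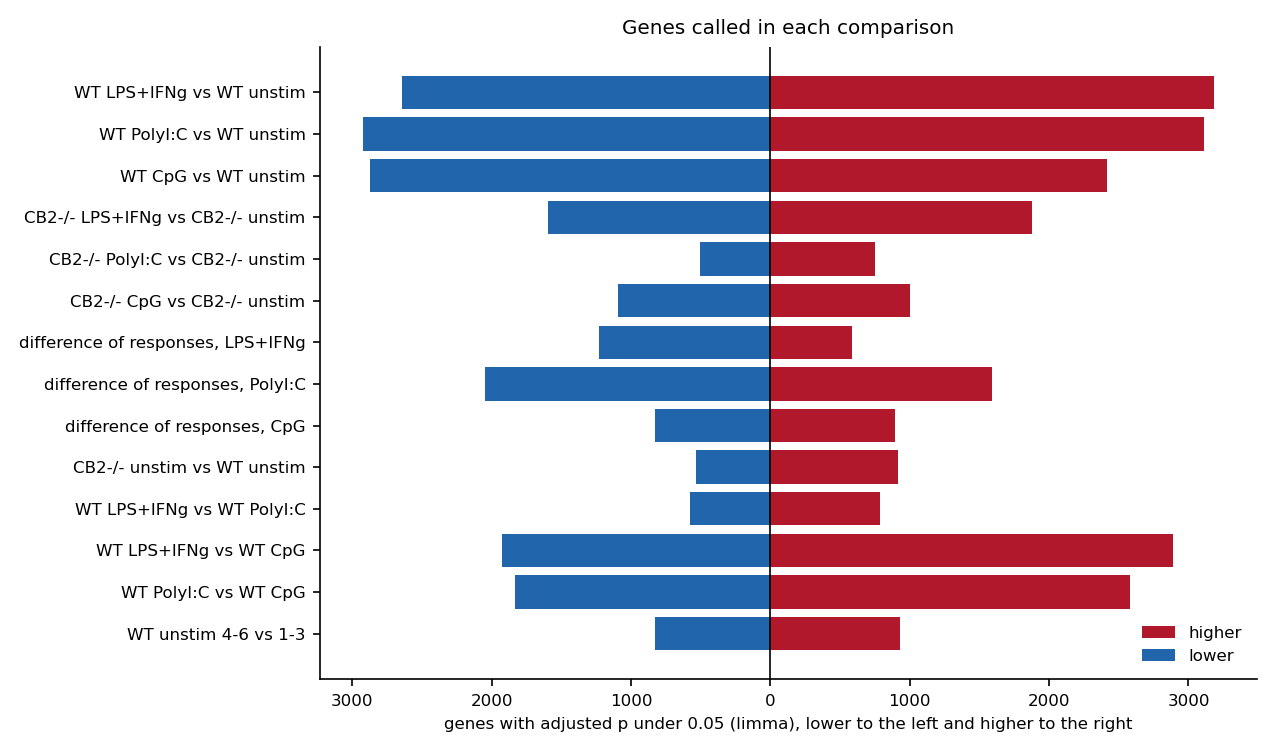
Number of genes with an adjusted p under 0.05 (limma, BH) in each comparison, lower genes to the left of 0 and higher genes to the right. Wild-type responses reach 6032 genes with PolyI:C, against 1254 in the libraries labelled CB2-/-, and 3636 genes differ in that response between the genotypes.

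A targeted gene is often flanked by sequence of the donor strain, so the genes within 10 Mb of Cnr2 were counted in the comparison without stimulus. There 37 of 230 genes (16.1%) passed the threshold, against 1415 of 14423 elsewhere (9.81%), an odds ratio of 1.76 (Fisher's exact test, two-sided, p = 0.00351). The genes with the smallest adjusted p were Marcksl1 (1.8 ± 0.22), the mannosidase Man1c1 (-1.18 ± 0.15) and C77080 (-5.62 ± 0.70, chromosome 4, 129219578 to 129261404), the largest of their adjusted p being 5.14e-06 (limma, BH). Over all stimuli C77080 ranged from 0 to 18.6 in the libraries labelled CB2-/- and from 4.69 to 325 in wild type, so these ranges overlapped. Within 2 Mb the odds ratio was 2.07 (Fisher's exact test, two-sided, p = 0.0620).

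Wild-type unstimulated libraries of the 2 number series were compared, replicates 4 to 6 minus 1 to 3, since labels give them the same treatment. Nos2 was higher in replicates 4 to 6 (313 ± 114 against 5.75 ± 5.42, 6.08 ± 0.82), as was H2-Ab1 (387 ± 83.6 against 23.8 ± 6.92, 3.99 ± 0.27), while Il1b (-2.56 ± 0.34) and Ccl5 (-1.76 ± 0.10) were lower, the largest adjusted p of the 4 genes being 1.23e-05 (limma, BH). Nos2 was higher by 5.01 without replicate 1 and by 6.79 without replicate 2. Cnr2 (-0.08 ± 0.54), Tnf (-0.24 ± 0.21) and Ifit1 (0.02 ± 0.17) had adjusted p of 0.955, 0.523 and 0.971 (limma, BH). Glycolysis and glucose uptake genes gave 17 of 20 higher and 0 lower (18 and 1 adjusted over the list alone), median log2 1.73, camera adjusted p = 1.23e-23, with Slc2a1 (2.37) and Pgk1 (2.32). Cholesterol genes gave 4 of 25 higher and 16 lower (4 and 18 adjusted over the list alone), median log2 -0.98, camera adjusted p = 2.00e-07, with Abcg1 (2.50) among the higher ones. Interferon response genes gave 1 of 31 higher and 9 lower (2 and 13 adjusted over the list alone), median log2 -0.45, camera adjusted p = 2.90e-04, adjusted p = 0.356 with an estimated correlation. Mitochondrially encoded transcripts gave 0 of 13 higher and 11 lower, median log2 -1.24, camera adjusted p = 2.14e-14. Astrocyte markers gave 0 of 12 higher and 0 lower, median log2 1.8, camera adjusted p = 0.0130, adjusted p = 0.979 with an estimated correlation. Between the series 1758 genes passed the threshold, 928 higher and 830 lower (limma, BH).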

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

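The tests of explanations and splits of libraries given here were all chosen after the result was seen. Responses to all 3 stimuli differed between the libraries labelled CB2-/- and wild type when the difference itself was tested (limma, BH). Gene counts were 1810 for LPS with interferon-γ, 3636 for PolyI:C and 1726 for CpG. Of 100 splits drawn per stimulus, only the real one gave as many genes for LPS and PolyI:C (highest other 1330 and 2357). For CpG 7 did (highest other 2311). The splits regroup libraries that differ by genotype and number series also without stimulus, so none is free of that difference. For LPS and PolyI:C they exclude only that a grouping made without regard to genotype gave as many genes. For CpG the share does not exclude chance, but the 6 others all parted the stimulated libraries by genotype and so hold the difference themselves. Splits that mixed both the stimulated and the unstimulated libraries, with that difference in their spread, called at most 2 genes.

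The smaller response of the libraries labelled CB2-/- to LPS and PolyI:C may have several sources. The slope of their changes on those of wild type was 0.520 ± 0.0187 for LPS, 0.201 ± 0.00773 for PolyI:C and 0.405 ± 0.0481 for CpG. CpG exceeded PolyI:C by 0.204 ± 0.0463 (jackknife over libraries). The slopes rest on different genes, so this argues only weakly against a common compression of changes as sole source, and it may contribute. With astrocyte and fibroblast markers as covariate, the median PolyI:C difference over cytokines, chemokines and interferon genes was -2.90 ± 0.32 (-2.88 ± 0.33 without). Cells that respond to PolyI:C escape such a covariate, so both types stay open. With the series difference removed, the stimulated level of the 31 interferon response genes differed by 0.232 ± 0.287 for LPS, as a higher unstimulated level alone would give, but by -0.804 ± 0.233 for PolyI:C, which it would not. Nor would it give the -2.37 ± 0.334 for PolyI:C of the 35 cytokines and chemokines, nor, less firmly, their -1.22 ± 0.516 for LPS (-0.604 without wild-type unstimulated replicate 4, and -0.791 ± 0.0841 as deposited). A difference in the cells, stimuli or preparation between the number series stays open, since unstimulated wild type differed by a median of 1.73 for glycolysis genes, as does the genotype itself.

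Gene lists whose LPS with interferon-γ response differed by camera had median log2 differences of proinflammatory cytokines -2.24, chemokines -2.33, type I interferon response -1.81, interferon-gamma response GTPases -2.14, MHC class I presentation -0.68, costimulatory and checkpoint molecules -1.48, NF-kB and feedback regulators -0.36, nitric oxide oxidant and itaconate enzymes -1.41, disease-associated microglia -0.53, alternative activation and anti-inflammatory -0.99, phagocytosis and Fc receptors -0.69, complement -0.74, inflammasome and cell death -0.39, glycolysis and glucose uptake -1.39, oxidative phosphorylation (nuclear) -0.28, unfolded protein and heat shock response -1.0, MAPK immediate-early genes -0.94 and matrix and proteases -1.50 on the lower side, and of homeostatic microglia 0.69 and cholesterol biosynthesis and efflux 1.52 on the higher side. The adjusted p with an estimated correlation was proinflammatory cytokines 0.128, costimulatory 0.181, nitric oxide 0.0997, homeostatic microglia 0.130, disease-associated microglia 0.181, alternative activation 0.181, complement 0.156, glycolysis 0.0959, oxidative phosphorylation (nuclear) 0.388, MAPK immediate-early genes 0.213 and matrix 0.181. Single genes with a higher LPS with interferon-γ response in the libraries labelled CB2-/- were Capn3 4.24, Il4i1 4.15, Col27a1 4.03, Abhd15 3.99, Pxdc1 3.96, Tmem119 3.63, Tmem176b 3.60, Csad 3.53 and Cnr2 2.54 (log2 difference). Those with a lower one were Nos2 -8.93, Ccl7 -7.62, Pdpn -7.01, Ccl2 -6.96, Mmp13 -6.80, AA467197 -5.93, Upp1 -5.92, Cd40 -2.19, Cd86 -2.17, Tnf -3.16, Il6 -5.33, Ifit1 -2.31, Cxcl10 -4.46, Ccl5 -0.84 and H2-Ab1 -3.03. On the log2(value + 1) scale Il12rb1 differed by -6.32 and Il12b by -3.29, no fold because a group is listed at 0.

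Gene lists whose PolyI:C response differed by camera had median log2 differences of proinflammatory cytokines -2.99, chemokines -2.90, type I interferon response -2.82, interferon-gamma response GTPases -2.94, MHC class I presentation -1.32, costimulatory and checkpoint molecules -1.94, NF-kB and feedback regulators -1.91, nitric oxide oxidant and itaconate enzymes -2.46, phagocytosis and Fc receptors -0.65, inflammasome and cell death -1.15, glycolysis and glucose uptake -1.15, unfolded protein and heat shock response -1.27, matrix and proteases -2.63 and monocytes and neutrophils -3.44 on the lower side, and of homeostatic microglia 1.62 and cholesterol biosynthesis and efflux 2.03 on the higher side. The adjusted p with an estimated correlation was costimulatory 0.196, phagocytosis 0.195, glycolysis 0.274 and matrix 0.239. Single genes with a higher PolyI:C response in the libraries labelled CB2-/- were Slco2b1 6.45, Htra3 6.16, Capn3 5.94, Mlxipl 5.55, Tmem37 5.52, Hpgd 5.47, Cxcr4 5.36, AF529169 5.32, P2ry12 2.05, Tmem119 4.37 and Cnr2 4.13 (log2 difference). Those with a lower one were Mmp13 -8.88, Pdpn -8.63, Il10 -8.43, Il6 -8.29, Ccl7 -8.21, Nos2 -7.71, Cd40 -4.44, Cd86 -1.07, Tnf -4.72, Ifit1 -4.10, Cxcl10 -6.18, Ccl5 -2.12 and H2-Ab1 -2.25. On the log2(value + 1) scale Il19 differed by -9.63, Draxin by -7.88 and Il12b by -5.08, no fold because a group is listed at 0.

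Gene lists whose CpG response differed by camera had median log2 differences of phagocytosis and Fc receptors -0.36, glycolysis and glucose uptake -0.37, unfolded protein and heat shock response -0.63, matrix and proteases -0.98 and ribosomal proteins -0.22 on the lower side, and of type I interferon response 0.50, MHC class I presentation 0.37, TLR receptors and signalling 0.45, homeostatic microglia 0.70 and cholesterol biosynthesis and efflux 0.74 on the higher side. The adjusted p with an estimated correlation was type I interferon response 0.564, MHC class I presentation 0.438, homeostatic microglia 0.438, phagocytosis 0.378, glycolysis 0.658, unfolded protein 0.438, matrix 0.438 and ribosomal proteins 0.564. Single genes with a higher CpG response in the libraries labelled CB2-/- were CT009754.3 6.39, Slc40a1 5.94, Cytip 5.88, Cdk5r1 5.79, Entpd1 5.38, Arg2 5.37, Cnr2 5.36, Amz1 4.78, Cd86 1.05, Il1b 3.12, Ccl5 1.20 and P2ry12 2.84 (log2 difference). Those with a lower one were Prss46 -6.12, Ndrg1 -5.42, Mmp9 -5.41, Ifitm7 -4.66, Raver2 -4.66, Mmp13 -4.65, Ccl7 -4.57 and Tnf -1.29. On the log2(value + 1) scale Draxin differed by -6.14, no fold because a group is listed at 0.

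Wild-type unstimulated replicate 3 stood apart from the other 5 libraries of its group in depth, at about 17.8 M reads against 3.96 to 7.80 M. The gap was 0.722 of the range, above Dixon's critical value for 6 libraries. It was 1 of 52 measures tested, and chance alone picks about 1 in 20.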

How the results depend on the processing

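Of the alternatives given here, the 3 that concern other-cell markers and libraries rich in Gm19220, Gm26822 and Grip2 were chosen after seeing the data. Over 7268 repeats of 353 results for named genes, 6907 kept their side of the threshold, 257 missed it and 102 newly passed it. A further 2, called before or after, turned sign. Results called neither before nor after counted as kept even where their sign turned. Il12b did so for PolyI:C against CpG, from -0.34 to 0.52 without wild-type PolyI:C replicate 1. The cause of the changes was not tested unless given. Counts of genes changed by over 1.5 times under these settings (limma, BH). With only the compared libraries in the fit, which estimates the spread from fewer samples, they were 2673 (wild-type CpG), 3299 (CpG, labelled CB2-/-), 911 (unstimulated genotypes), 2022 (PolyI:C against CpG) and 657 (number series). Library weights gave 5603 (LPS, labelled CB2-/-), 2040 (PolyI:C, labelled CB2-/-), 4158 (CpG, labelled CB2-/-), 4453 (difference in LPS response), 5528 (difference in PolyI:C response), 2967 (difference in CpG response), 2543 (unstimulated genotypes), 2755 (LPS against PolyI:C) and 3232 (number series). A fold change of at least 2, which can only remove genes, left 3713 (wild-type LPS), 3867 (wild-type PolyI:C), 3114 (wild-type CpG), 1873 (LPS, labelled CB2-/-), 462 (PolyI:C, labelled CB2-/-), 1048 (CpG, labelled CB2-/-), 1102 (difference in LPS response), 1041 (difference in CpG response), 537 (unstimulated genotypes), 614 (LPS against PolyI:C), 2903 (LPS against CpG), 2473 (PolyI:C against CpG) and 792 (number series). The authors' batch-corrected table on a log2 scale gave 2249 (PolyI:C, labelled CB2-/-), 3032 (difference in LPS response), 4993 (unstimulated genotypes) and 2179 (LPS against PolyI:C); there Il6 turned from -0.84 to 0.92 in the CpG difference (adjusted p = 0.0204, limma, BH), and Cnr2 was higher in the unstimulated libraries labelled CB2-/- by 0.94 (adjusted p = 1.33e-06, limma, BH). Without the series term 2209 genes differed between the unstimulated genotypes, and H2-Ab1 turned to -0.12 with CpG in wild type (adjusted p = 0.922, limma, BH). Without the 4 libraries over 20% in Gm19220, Gm26822 and Grip2 the counts were 773 (PolyI:C, labelled CB2-/-), 213 (unstimulated genotypes) and 918 (number series), the last pair with 1 wild-type library of replicates 4 to 6 left, assumed to vary like the other groups, and with the marker covariate 2279 (unstimulated genotypes). Of 307 called results of named genes, 116 moved by over 1.5-fold without some single library, most often wild-type CpG replicate 1 (33), unstimulated replicate 1 (27) or PolyI:C replicate 1 (25). Camera called 218 list tests, 110 with an estimated correlation. Within 2 Mb of Cnr2 the odds ratio was 2.07. Leaving out each library in turn gave 5075 to 5599 (wild-type LPS), 5460 to 5643 (wild-type PolyI:C), 4461 to 5366 (wild-type CpG), 2788 to 2905 (LPS, labelled CB2-/-), 805 to 1041 (PolyI:C, labelled CB2-/-), 1619 to 1706 (CpG, labelled CB2-/-), 1434 to 1923 (difference in LPS response), 3195 to 3709 (difference in PolyI:C response), 1308 to 2132 (difference in CpG response), 819 to 1976 (unstimulated genotypes), 943 to 1249 (LPS against PolyI:C), 4040 to 5182 (LPS against CpG), 3837 to 4540 (PolyI:C against CpG) and 1256 to 1924 (number series). Over 1.5 times from the full count lay 2 counts for PolyI:C, labelled CB2-/-, and 3 for the unstimulated genotypes, all given above. No paired analysis was possible, since no label gives a shared animal, culture or day. Tests on reads (edgeR, DESeq2) were not run for lack of whole reads.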

Other observations

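The tests of explanations and the splits given here were chosen after the result was seen, except the scan of windows along the genome, which was set before. Inflammasome and cell death genes rose with LPS and interferon-γ in wild type, with Casp4 (3.45), Mlkl (5.40) and Fas (4.11) as examples: 20 of 24 higher and 0 lower (20 and 1 adjusted over the list alone), median log2 1.75, camera adjusted p = 7.30e-10. With PolyI:C in wild type they gave 20 of 24 higher and 3 lower, median log2 1.81, camera adjusted p = 2.83e-09. LPS in the libraries labelled CB2-/- gave 16 of 24 higher and 1 lower (17 and 1 adjusted over the list alone), median log2 1.11, camera adjusted p = 1.08e-09. TLR receptors and signalling genes gave 10 of 25 higher and 4 lower (12 and 4 adjusted over the list alone), median log2 0.42, camera adjusted p = 0.00410 with LPS in the libraries labelled CB2-/-. Matrix genes and proteases with CpG in wild type gave 11 of 22 higher and 2 lower (13 and 2 adjusted over the list alone), median log2 1.47, camera adjusted p = 5.05e-05, adjusted p = 0.308 with an estimated correlation.

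Type I interferon response genes stood higher in the unstimulated libraries labelled CB2-/- than in wild type. Other cells diluting microglial transcripts in wild type are argued against, since the highest median of the homeostatic, phagocytosis and TLR lists was 0.15 against 1.75 for the interferon list. Nor do 3 wild-type libraries standing apart account for it: for 29 of 31 genes all 3 libraries labelled CB2-/- lay above all 6 wild-type ones. Library preparation may differ, since mitochondrially encoded transcripts also differed by -1.0 ± 0.268, and preparation and genotype cannot be told apart. A response of the cultures before harvest also stays open, untested.

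Calls between the unstimulated genotypes were frequent near Cnr2, and flanking donor-strain sequence is a candidate explanation. Around Cnr2 37 of 230 genes were called, more than in 96.3% of 10031 overlapping windows of as many consecutive genes (median 23, highest 43). The windows share genes and other regions reached as many calls, so neighbouring genes regulated together stay open.

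For the 11 comparisons of 3 against 3 libraries, the 10 possible splits are too few for a share under 0.05. The real count and the highest of the other splits were 5830 and 1 for wild-type LPS, 6032 and 246 for wild-type PolyI:C, 5285 and 831 for wild-type CpG, 3471 and 2 for LPS, labelled CB2-/-, 1254 and 14 for PolyI:C, labelled CB2-/-, 2092 and 0 for CpG, labelled CB2-/-, 1452 and 2 for unstimulated genotypes, 1358 and 1 for LPS against PolyI:C, 4812 and 3 for LPS against CpG, 4412 and 439 for PolyI:C against CpG and 1758 and 146 for number series.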
